A study of Pseudomonas aeruginosa PAO1
Aspergillus fumigatus A1163 and Aspergillus fumigatus A1163 with 27 samples.

How the data were processed

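Libraries were made from poly(A)-selected RNA of fungal mycelium and sequenced as paired-end reads of 100 bp, per the labels' protocols. The deposited file is 1 table of raw counts per gene, with 10160 genes and a column for each of the 27 libraries. CASAVA and HTSeq are named in the submitters' processing notes, with no version or setting. The aligner, the genome build and whether counting used strand are not given in the sources used here, so overlapping genes and near-identical copies could share or lose reads. All columns carried a library title, and 0 columns were left unused. Bacterial transcripts were not analysed here.

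Each library was placed in its group by its title, which gives the replicate number, the culture condition and the time. Replicates were compared before use. The smallest chi-square per degree of freedom among the 27 pairs was 3.73, and 0 pairs held identical values, so that every library was counted on its own. Total counts ran from 3666541 to 5980235. Of the 10160 genes, 105 had no count in any library and 8332 passed the edgeR filter on low counts (filterByExpr by group). These 8332 genes held 99.9% or more of the counts in each library. The 2 most abundant features together took 5.85% to 28.1% of the counts in 26 libraries and 49.2% in replicate 1 of the cocultures at 90 min. Library totals were therefore scaled with TMM factors, which ran from 0.508 to 1.17.

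The main test was edgeR's quasi-likelihood F test, 2-sided, with robust dispersion estimates in 1 fit of all 27 libraries and 9 group means, which left 18 residual degrees of freedom. The common biological coefficient of variation was 14.8%, and 12.0% without the 2 heat-inactivated libraries that lay at another time point. Genes with a Benjamini-Hochberg adjusted p under 0.05 over the tested genes were called. The 13 comparisons planned were bacteria against mycelium alone at each time for untreated and for heat-inactivated cells, untreated against heat-inactivated cells at each time, 90 and 180 against 45 min in mycelium alone, and 2 interactions of bacteria with time. A further 5 comparisons over time were added after the data were seen. Levels are CPM on the TMM-scaled totals. Intervals of fold changes are 95% intervals from the t distribution with the degrees of freedom of the fit, not adjusted for the number of genes. Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.

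Before the data were examined, a rule fixed which genes to name: called, a mean of at least 10 CPM over the compared libraries, and all 3 libraries of 1 group above all 3 of the other. Where identifiers had no names, at most 2 that rose and 2 that fell were to be given per comparison, those with the largest change. The reference table of 5697 genes supplied here was of the bacterium, *Pseudomonas aeruginosa* PAO1, so it could not match the fungal identifiers, and it matched 0 of them. For that reason none of the 40 gene lists fixed in advance, including the markers of conidia and of conidial melanin, could be matched to the table, and no test of gene lists was run.

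Alternatives planned before the data were examined were RLE size factors, no scaling factor beyond the library total, no filter on low counts, the replicate number as a block, a fit of only the compared groups, DESeq2's Wald test, and leaving out each library in turn. Leaving out the 2 heat-inactivated libraries, with and without the block, was added after the data were seen. The fit was tested on simulated counts for the 8332 genes, in 5 sets with 200 genes changed in each, drawn with the real means and library sizes. The changed genes were taken from those with an average level over 2 CPM. For coculture against mycelium alone at 45, 90 and 180 min it recovered 37.0%, 34.9% and 38.8% of genes changed 1.5-fold, 77.9%, 76.4% and 75.2% of those changed 2-fold, and 94.9%, 96.1% and 96.7% of those changed 4-fold. False calls were 3.32%, 4.03% and 5.40% of all calls, and 0 had the wrong sign. Other splits of the libraries, the order of identifiers and the place of libraries along the time course were tested as described with their results.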

Results

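The series measured poly(A)-selected RNA from the mycelium of *Aspergillus fumigatus* A1163, a filamentous fungus and opportunistic pathogen of the lung. The question was how fungal transcripts differ when the mycelium shares its medium with *Pseudomonas aeruginosa*, a bacterium found in the same airways. Mycelium grown for 12 h at 37 °C was moved to 100 ml of fresh minimal medium and then kept alone, with 1000000000 untreated *Pseudomonas* cells, or with as many heat-inactivated cells. RNA was sampled 45, 90 and 180 min later. The 3 culture conditions and 3 times made 9 groups of 3 libraries, 27 in all. The labels number the replicates but do not say that they were separate cultures, so the p-values measure only the spread between these libraries, which may be technical. Total counts ran from 3666541 to 5980235 per library, with a median of 5246434, and 8977 to 9342 of the 10160 genes had a count. Genes carry identifiers that the files do not pair with names, so no gene below has a known function here, and at most 2 identifiers that rose and 2 that fell are given per comparison.

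Time after transfer separated the libraries far more than the bacteria did. On the first 2 principal components, which held 50.5% and 12.8% of the variance, libraries lay by time. Within a time the 3 culture conditions lay closer together than the times did. Exceptions were 2 libraries of the heat-inactivated condition. Replicate 2 labelled 45 min lay among the 90 min libraries (PC1 -3.81, PC2 19.8), and replicate 3 labelled 90 min lay among the 45 min libraries (PC1 -36.2, PC2 -14.1). Both stayed in the planned comparisons under their labels. The count of genes called in each comparison was also computed with both left out, an alternative chosen after the data were seen. At 45 min PC2 ran from -7.27 to -2.58 in the cocultures and from -14.2 to -10.4 in mycelium alone. The other heat-inactivated libraries lay at -12.2 and -9.31. At 90 min PC1 ran from -5.66 to -1.20 in mycelium alone and from 0.332 to 7.54 in the cocultures. The other heat-inactivated libraries lay at 3.89 and 2.55. Cocultures and mycelium alone overlapped at the last time. These differences were picked after the scores were seen and were not tested.

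**Figure D1:**
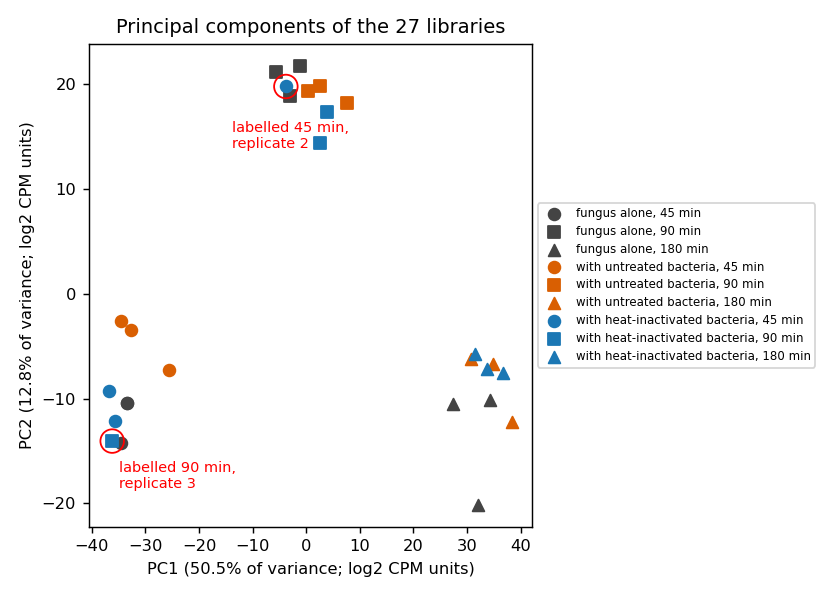
Scores of the 27 libraries on the first and second principal components of log2 CPM over the tested genes; each point is 1 library, coloured by culture condition and shaped by time. The 2 circled libraries of the heat-inactivated condition lie with the other time point, at PC1 -3.81 (labelled 45 min) and -36.2 (labelled 90 min).

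In mycelium alone, 761 of the 8332 tested genes rose and 519 fell from 45 to 90 min, and 347 of the risers and 124 of the fallers changed at least 2-fold. CADAFUBG00006587 rose from 5.003 ± 1.51 to 43.6 ± 2.19 CPM (SD, n = 3 libraries each; log2 fold change 3.13, SE 0.631; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00411). CADAFUBG00004887 rose from 2.91 ± 0.772 to 22.04 ± 3.88 CPM (log2 fold change 2.93, SE 0.706; edgeR, Benjamini-Hochberg adjusted p = 0.00965). CADAFUBG00007757 went the other way, from 30.8 ± 2.86 to 5.07 ± 0.341 CPM (log2 fold change -2.60, SE 0.714; edgeR, Benjamini-Hochberg adjusted p = 0.0197). CADAFUBG00006732 fell from 228 ± 146 to 40.3 ± 6.93 CPM, with a wide spread at 45 min (log2 fold change -2.50, SE 0.725; edgeR, Benjamini-Hochberg adjusted p = 0.0255). The count of 1280 genes became 1903 with the 2 heat-inactivated libraries left out, 2366 when only the compared groups entered the fit, and 671 to 783 with any 1 of the 6 compared libraries left out. Scaling by library totals alone gave 572 genes, of which 455 rose and 117 fell.

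By 180 min the change in mycelium alone was wider, with 1635 genes higher and 1128 lower than at 45 min. Of these, 771 rose and 210 fell at least 2-fold, and 232 rose and 61 fell at least 4-fold. CADAFUBG00008670 rose from 1.66 ± 2.88 to 225 ± 52.9 CPM (SD, n = 3 libraries each; log2 fold change 6.95, SE 0.724; edgeR, Benjamini-Hochberg adjusted p = 3.21e-06). Its counts at 45 min were 30, 0 and 0, so that level, and with it the size of the fold change, rests on replicate 1. CADAFUBG00008672 rose from 26.5 ± 26.4 to 1711 ± 798 CPM (log2 fold change 6.002, SE 0.949; edgeR, Benjamini-Hochberg adjusted p = 0.000136). CADAFUBG00000122 fell from 695 ± 202 to 33.8 ± 9.38 CPM (log2 fold change -4.35, SE 0.379; edgeR, Benjamini-Hochberg adjusted p = 3.42e-07), and CADAFUBG00001508 fell from 1138 ± 205 to 55.6 ± 24.96 CPM (log2 fold change -4.34, SE 0.506; edgeR, Benjamini-Hochberg adjusted p = 8.16e-06). The 1635 risers together took 13.5% ± 0.266 of all counts at 45 min and 21.1% ± 2.33 at 180 min (SD, n = 3), and the 1128 fallers went from 15.6% ± 0.737 to 8.58% ± 1.53. Among the called genes, 5 had no count in any of the 3 libraries at 45 min. A count of 0 over that group allows up to 3 counts, or 0.182 CPM, so these 5 genes were at least 6.25-fold to 23.7-fold higher at 180 min; these bounds cover counting error only. Scaling by library totals alone gave 1723 genes, with 654 higher and 1069 lower.

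A comparison of 180 with 90 min in mycelium alone, added after the data were seen, called 895 genes as rising and 596 as falling. This balance turned when counts were scaled by library totals alone, with 183 higher and 573 lower. The count of 1491 was 935 when only the compared groups were fitted and 891 to 1541 with any 1 compared library left out, the lowest being 891, 912 and 946 without replicate 1 at 90 min, replicate 2 at 180 min and replicate 3 at 90 min. Of the genes called in this later interval, 714 that rose and 513 that fell were not called from 45 to 90 min, and whether their change differed between the intervals was not tested. A further 44 were called as rising in both intervals and 11 as falling in both. Changes that turned back were called for 72 genes that rose by 90 min and then fell, with median log2 fold changes of 0.75 and -0.77, and for 137 genes that fell by 90 min and then rose, with medians of -0.65 and 0.76. In the cocultures, whose libraries shared the fit and its spread but were not among those compared to choose these genes, 56 of the 72 and 119 of the 137 moved in the same 2 directions. That was 77.8% and 86.9%, against 28.6% and 21.6% of all tested genes, although edgeR called both steps in the cocultures for 4 and 12 of them.

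Over the whole course the cocultures with untreated bacteria passed through much the same change, in a comparison added after the data were seen. From 45 to 180 min, 1531 genes rose and 1065 fell in the cocultures, and scaling by library totals alone gave 733 higher and 557 lower. Of the 2763 genes called in mycelium alone, 1182 were called as rising and 618 as falling in both, 0 were called in opposite directions, and 2709 (98.0%) had the same sign. Independent lists of these sizes would share 300.4 and 144.2. Across all tested genes the log2 fold changes had Pearson's r = 0.895, and genes are not independent replicates. CADAFUBG00008670 rose by 8.45 and CADAFUBG00008672 by 6.60 on the log2 scale in the cocultures, to 177 ± 75.6 and 1424 ± 763 CPM at 180 min (SD, n = 3). From 45 to 90 min, 429 genes rose and 463 fell in the cocultures; this count of 892 became 1672 with the 2 heat-inactivated libraries left out and 116 to 455 with any 1 of the 6 compared libraries left out. Scaling by library totals alone gave 58 higher and 574 lower genes for that step. Of the 1280 genes called in mycelium alone from 45 to 90 min, 231 were called as rising and 186 as falling in both, and 0 in opposite directions. The same sign was seen for 1207 (94.3%). Pearson's r across all tested genes was 0.722, lower than over 45 to 180 min. With heat-inactivated bacteria, 1296 genes rose and 1007 fell from 45 to 180 min. That count of 2303 was 1318 to 2666 with any 1 compared library left out, and the 45 min group held 1 library that lay among the 90 min libraries. Of the 2763 genes, 999 were called as rising in both and 606 as falling in both, and 4 were called in opposite directions. Scaling by library totals alone gave 1431 genes there, with 467 higher and 964 lower.

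**Figure D2:**
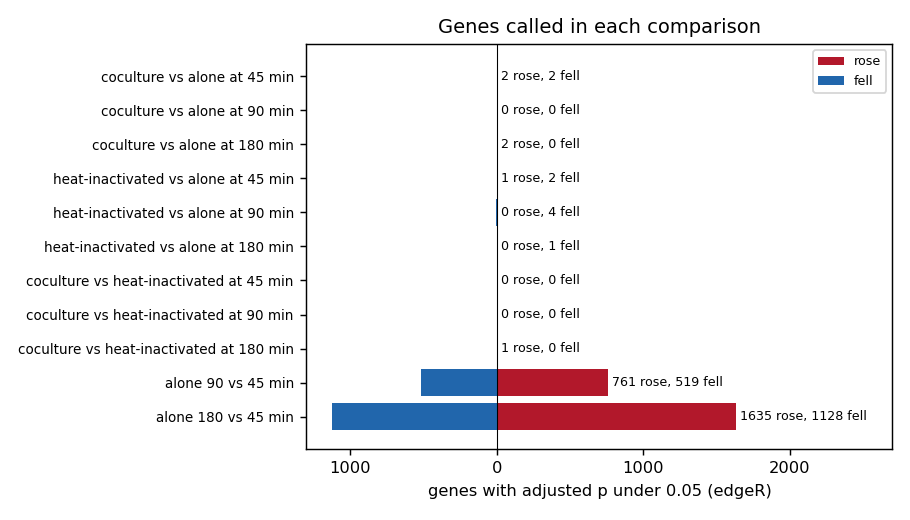
Number of genes past the adjusted threshold in 11 planned comparisons, with genes that rose to the right of 0 and genes that fell to the left, from the edgeR fit of all 27 libraries. The comparisons with bacteria called 0 to 4 genes each, and the 2 comparisons over time called 1280 and 2763.

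Against this change over time, few genes differed between mycelium with untreated bacteria and mycelium alone at the same time. At 45 min 2 genes rose and 2 fell, and 548 had an unadjusted p under 0.05 in edgeR's test, where chance alone would give 417. CADAFUBG00002951 was at 16.8 ± 3.45 CPM in the cocultures and 7.37 ± 1.54 CPM alone (SD, n = 3 libraries each; log2 fold change 1.18, SE 0.218; edgeR, Benjamini-Hochberg adjusted p = 0.0347). CADAFUBG00006220, named after its values were seen because it lies under the minimum of 10 CPM, was at 7.40 ± 0.614 against 2.43 ± 0.331 CPM (log2 fold change 1.60, SE 0.281; edgeR, Benjamini-Hochberg adjusted p = 0.0267). CADAFUBG00007065 fell from 185 ± 20.3 CPM alone to 92.2 ± 9.27 CPM (log2 fold change -1.004, SE 0.138; edgeR, Benjamini-Hochberg adjusted p = 0.00102), and CADAFUBG00001245 fell from 239 ± 58.4 to 131 ± 4.29 CPM (log2 fold change -0.87, SE 0.168; edgeR, Benjamini-Hochberg adjusted p = 0.0446). For these 2 genes mycelium alone was at 87.9 ± 7.28 and 105 ± 3.55 CPM at 90 min, and at 256 ± 39.9 and 187 ± 19.1 CPM at 180 min. The count of 4 became 92 with the 2 heat-inactivated libraries left out, neither of which is in this comparison. They could act on it only through the shared fit, whose common biological coefficient of variation was 14.8% with them and 12.0% without. The count was 92 as well when only the 6 compared libraries were fitted, as planned before the data were examined. In both lists of 92 were 65 genes, with the same direction. The count was 10 with DESeq2, 0 when scaled by library totals alone, and 1 to 2 with any 1 compared library left out. With the 2 heat-inactivated libraries left out and the replicate number as a block, it was 176.

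With those 2 libraries left out, 73 genes rose and 19 fell at 45 min. These differences were small, with log2 fold changes from -1.39 to 1.60 and medians of 0.72 among the risers and -0.69 among the fallers. At least a 2-fold change was seen for 12 risers and 2 fallers.

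At 90 min edgeR called 0 genes between mycelium with untreated bacteria and mycelium alone; 299 had an unadjusted p under 0.05, where chance alone would give 417, and DESeq2 also called 0. The count was 2 with the 2 heat-inactivated libraries left out and 4 when only the compared groups were fitted. At 180 min 2 genes rose and 0 fell, with 523 genes at an unadjusted p under 0.05 and 5 genes called by DESeq2. CADAFUBG00006852 was at 19.6 ± 4.15 CPM with untreated bacteria and 7.83 ± 1.41 CPM alone (SD, n = 3; log2 fold change 1.30, SE 0.223; edgeR, Benjamini-Hochberg adjusted p = 0.0263). CADAFUBG00007754 was at 44.1 ± 3.88 against 23.8 ± 6.71 CPM (log2 fold change 0.90, SE 0.159; edgeR, Benjamini-Hochberg adjusted p = 0.0263). Leaving out any of 5 of the 6 compared libraries gave 0 genes, and leaving out replicate 1 of mycelium alone gave 7. The count was 5 with the 2 heat-inactivated libraries left out, and 0 when scaled by library totals alone or when only the compared groups were fitted. With those 2 libraries left out and the replicate number as a block, it was 21.

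These low counts came with a bound on the size of most effects. The 95% interval of the log2 fold change between mycelium with untreated bacteria and mycelium alone lay within a 2-fold change either way for 84.4% of the tested genes at 45 min, 85.9% at 90 min and 84.6% at 180 min. In simulated data the same comparisons recovered 77.9%, 76.4% and 75.2% of genes changed 2-fold at these times, and 37.0%, 34.9% and 38.8% of genes changed 1.5-fold. Those simulations changed 200 genes at once, all with an average level over 2 CPM. The adjusted threshold is looser when many genes change, so recovery where few genes change, or at lower levels, was not measured and may be lower.

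**Figure D3:**
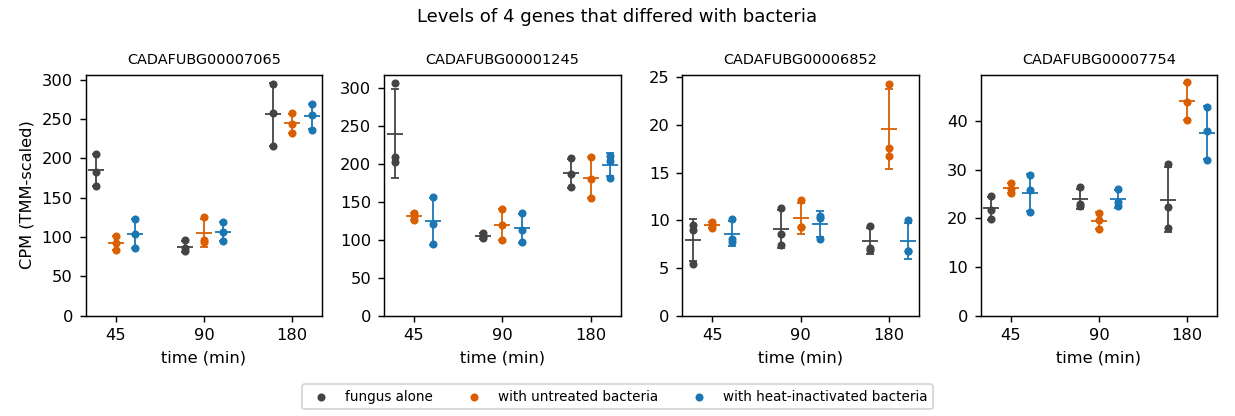
CPM of 4 genes that differed with bacteria, against time in minutes; points are libraries, horizontal marks are means and bars are SDs of 3 libraries, coloured by culture condition. CADAFUBG00007065 and CADAFUBG00001245 were lower with bacteria at 45 min, CADAFUBG00007754 was higher with untreated bacteria than alone at 180 min, and CADAFUBG00006852 was higher at 180 min with untreated bacteria (19.6 CPM) than alone (7.83 CPM) or with heat-inactivated cells (7.86 CPM).

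With all libraries in the fit, heat-inactivated cells gave counts of called genes of the same order. In edgeR's test 738, 658 and 643 genes had an unadjusted p under 0.05 against mycelium alone at 45, 90 and 180 min. Chance alone would give 417 each time, and untreated bacteria gave 548, 299 and 523. Genes are not independent, and whether the excess was more than chance was not tested. At 45 min 1 gene rose and 2 fell against mycelium alone. CADAFUBG00008886 was at 38.4 ± 5.06 CPM against 17.7 ± 0.465 CPM (SD, n = 3; log2 fold change 1.12, SE 0.170; edgeR, Benjamini-Hochberg adjusted p = 0.00592). The 2 genes that fell were the same 2 that fell with untreated bacteria. CADAFUBG00001245 was at 124 ± 30.9 CPM with heat-inactivated cells (log2 fold change -0.95; edgeR, Benjamini-Hochberg adjusted p = 0.0201) and CADAFUBG00007065 at 104 ± 18.2 CPM (log2 fold change -0.83; edgeR, Benjamini-Hochberg adjusted p = 0.0111). Without the 2 heat-inactivated libraries that lay at another time, 1 gene was called, and for CADAFUBG00001245 and CADAFUBG00007065 the edgeR adjusted p was 0.126, at log2 fold changes of -0.78 and -0.70. With the replicate number as a block in that reduced set, 11 genes were called, among them all 3 called with all libraries. With only 1 compared library left out, the count was 0 without replicate 3 of mycelium alone, 0 without heat-inactivated replicate 2, 1 without heat-inactivated replicate 1 and 3 in the other 3 cases. Untreated bacteria at 45 min gave 92 genes in the reduced set and 176 with the block. The counts of 45 min were thus not of the same order there, although the heat-inactivated group then held only 2 libraries. Fitting only the compared groups gave 92 genes with untreated and 0 with heat-inactivated bacteria, with the misplaced library kept. At the later times the reduced set gave 2 and 5 genes with untreated and 3 and 4 with heat-inactivated bacteria. With the block as well, it gave 2 and 21 with untreated and 17 and 40 with heat-inactivated bacteria.

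At 90 min 0 genes rose and 4 fell with heat-inactivated cells. CADAFUBG00000566 was at 5.43 ± 0.877 CPM against 14.6 ± 1.46 CPM alone (SD, n = 3; log2 fold change -1.43, SE 0.241; edgeR, Benjamini-Hochberg adjusted p = 0.0219). CADAFUBG00009133 was at 26.6 ± 5.597 against 56.7 ± 7.77 CPM (log2 fold change -1.10, SE 0.190; edgeR, Benjamini-Hochberg adjusted p = 0.0219). DESeq2 called 26 genes, and leaving out 1 compared library gave 0 to 8, with 0 for 4 of the 6. Without the 2 libraries that lay at another time 3 genes were called, of which 1, CADAFUBG00009133, was among the 4, and CADAFUBG00000566 had an edgeR adjusted p of 0.0558 at a log2 fold change of -1.34. At 180 min the only gene called was CADAFUBG00003310, which fell from 77.04 ± 14.1 CPM alone to 44.7 ± 4.597 CPM (log2 fold change -0.78, SE 0.133; edgeR, Benjamini-Hochberg adjusted p = 0.0347). DESeq2 called 7 genes there, the count was 4 with the 2 libraries left out, and leaving out 1 compared library gave 0 to 15. All 3 counts with heat-inactivated cells were 0 when scaled by library totals alone or when only the compared groups were fitted. The 95% interval lay within a 2-fold change for 82.7%, 84.2% and 83.6% of genes at 45, 90 and 180 min.

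Untreated and heat-inactivated bacteria were set against each other to ask what live cells add. The gene CADAFUBG00006852 was the only one called, at 180 min, with 19.6 ± 4.15 CPM against 7.86 ± 1.87 CPM (SD, n = 3; log2 fold change 1.33, SE 0.225; edgeR, Benjamini-Hochberg adjusted p = 0.0284), and it rose against mycelium alone at that time too. DESeq2 called 2 genes at 180 min, edgeR called 2 with the 2 heat-inactivated libraries left out and 0 when scaled by library totals alone or when only the compared groups were fitted, and leaving out 1 compared library gave 0 for 4 of the 6 and 1 for the other 2. At 45 min edgeR called 0 genes, with 295 at an unadjusted p under 0.05 and 1 called by DESeq2. At 90 min edgeR called 0 genes, with 525 at an unadjusted p under 0.05 and 0 called by DESeq2. The heat-inactivated groups of 45 and 90 min each held 1 library that lay at the other time, so these 0 counts say little about what live cells add. The 95% interval lay within a 2-fold change for 85.6%, 82.4% and 86.6% of genes at the 3 times.

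The responses to untreated and to heat-inactivated bacteria shared 2 called genes, both at 45 min and both lower. With the 2 heat-inactivated libraries left out they shared 0 at 45 min, 2 that fell at 90 min and 1 that fell at 180 min. With all libraries, independent lists of these sizes would share 0.00048 falling genes at 45 min, and simulated unchanged groups set against the same control libraries shared 0. Over all tested genes the log2 fold changes of the 2 responses had a covariance of 0.0632 at 45 min, 0.0267 at 90 min and 0.0491 at 180 min. Simulated unchanged groups against the same controls gave 0.0393, 0.0358 and 0.0377. With the 2 heat-inactivated libraries left out the covariances were 0.0538, 0.0426 and 0.0506, against simulated values of 0.0367, 0.0287 and 0.0326, so that all 3 lay above the simulated ones. The correlations across genes were then 0.54, 0.53 and 0.64, against simulated values of 0.45, 0.40 and 0.51. The 3 control libraries per time were too few to be split, and part of the excess may come from the shared controls.

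Whether the effect of bacteria differed between 180 and 45 min was tested as an interaction. For untreated bacteria edgeR called 0 genes, with 435 at an unadjusted p under 0.05, and DESeq2 called 1. For heat-inactivated bacteria edgeR called 0 genes, with 541 at an unadjusted p under 0.05, and DESeq2 called 9. Without the 2 heat-inactivated libraries edgeR called 1 and 3, and 8 and 47 when the replicate number was a block as well. The answer thus depended on the fit.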

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

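The genes below were chosen for a difference with bacteria at 1 time and then tested for a change of that difference between 45 and 180 min, a test chosen after the results were seen. Such a choice enlarges the difference between times. Over all 8332 genes neither interaction called a gene with edgeR in the main fit, where the lowest adjusted p was 0.429 for untreated and 0.197 for heat-inactivated bacteria. With the 2 heat-inactivated libraries left out and the replicate number as a block, the interactions called 8 and 47 genes. Of the 20 tests of 10 named genes, 13 had a Benjamini-Hochberg adjusted p under 0.05 in edgeR's test over these 20 alone, from 0.000554 to 0.0257. Each group had 3 libraries, and no test of single outlying libraries was run for these genes.

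For untreated bacteria, 4 genes that differed at 45 min were back near the level of mycelium alone at 180 min. The log2 difference changed by -0.90 for CADAFUBG00002951 (from 1.18 to 0.28) and by -1.61 for CADAFUBG00006220 (from 1.60 to -0.02), and by 0.94 for CADAFUBG00007065 (from -1.004 to -0.07) and 0.83 for CADAFUBG00001245 (from -0.87 to -0.05). The opposite order was seen for 2 genes called at 180 min, CADAFUBG00006852 with a difference of 1.03 between the times and CADAFUBG00007754 with 0.66. For CADAFUBG00008886, called with heat-inactivated cells only, the difference was -0.64.

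For heat-inactivated bacteria, the same 4 genes of 45 min had differences of -0.85 (CADAFUBG00002951), -1.89 (CADAFUBG00006220), 0.81 (CADAFUBG00007065) and 1.03 (CADAFUBG00001245). CADAFUBG00008886 had a difference of -1.04, from 1.12 at 45 min to 0.07 at 180 min. CADAFUBG00003310 had -0.90, from 0.12 to -0.78. The heat-inactivated libraries labelled 45 min include 1 that lay among the 90 min libraries. Both interactions use the same libraries of mycelium alone, so these differences are no independent repeat of those with untreated bacteria.

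Regrouping the libraries in 100 ways, the real one included, gave at least as many genes as the real count of 0 in all 100 for both interactions, with at most 1 gene for untreated and 2 for heat-inactivated bacteria in any other regrouping. With a real count of 0 this outcome was fixed in advance, and it says nothing about chance.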

How the results depend on the processing

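Leaving out the 2 heat-inactivated libraries, and all alternatives of the 5 added comparisons over time, were chosen after the data were seen; the other alternatives were planned. No named gene reversed its direction: of 294 values of the 21 named pairs of gene and comparison under the alternatives, 209 stayed past the threshold and 85 did not. Scaling by library totals alone lost 14 of the 21 calls, a fit of only the compared groups 9, and leaving out the 2 heat-inactivated libraries 3; RLE size factors, no low-count filter, the block and DESeq2 lost 0. Counts stayed within 1.5 times of the main count under RLE size factors and without the filter, for each comparison. The planned tests of gene lists were not run, since the 40 lists could not be matched. The cause of the changes below was not tested, except where the construction gives it.

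Scaling by library totals alone gave 0 genes at 45 and 180 min for untreated bacteria, 0 at each time for heat-inactivated bacteria, and 0 for untreated against heat-inactivated at 180 min. It gave 572 (alone, 90 against 45 min), 1723 (alone, 180 against 45), 1290 (coculture, 180 against 45), 1431 (heat-inactivated, 180 against 45) and 756 (alone, 180 against 90). This setting moved the median log2 fold change of all genes by -0.29 for untreated bacteria at 90 min, by 0.19 at 180 min and by -0.26 for 180 against 45 min alone.

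Fitting only the compared groups gave 92 genes for untreated bacteria at 45 min, 4 at 90 min and 0 at 180 min, 0 at each time for heat-inactivated bacteria, 0 for untreated against heat-inactivated at 180 min, 2366 (alone, 90 against 45), 1671 (coculture, 90 against 45), 1417 (heat-inactivated, 180 against 45; 968 higher and 449 lower) and 935 (alone, 180 against 90). DESeq2 gave 10 and 5 for untreated bacteria at 45 and 180 min, 26 and 7 for heat-inactivated bacteria at 90 and 180 min, 1 and 2 for untreated against heat-inactivated at 45 and 180 min, and 1 and 9 for the interactions with untreated and heat-inactivated bacteria.

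Leaving out the 2 heat-inactivated libraries gave 92, 2 and 5 genes for untreated bacteria at 45, 90 and 180 min, 1 and 4 for heat-inactivated bacteria at 45 and 180 min, 2 for untreated against heat-inactivated at 180 min, 1 and 3 for the interactions, 1672 (coculture, 90 against 45) and 1457 (heat-inactivated, 90 against 45, where all libraries gave 0). The genes called with both kinds of bacteria numbered 2, and 0 when a 2-fold change was also required.

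Same-numbered libraries of different groups did not all deviate together: 46 of 108 pairs, or 44 of 92 without the 2 libraries, had a correlation over 0.1, and the lowest was -0.35. The numbers were not taken as pairs in the main fit. Still, 21 of the other 25 libraries correlated best with their own number. That points to an effect shared by same-numbered libraries, which the main fit leaves out. The replicate block moved 2 counts by over 1.5 times, to 2 for heat-inactivated bacteria at 180 min and to 1 for the heat-inactivated interaction. With the 2 libraries left out as well, the block gave 176, 2 and 21 for untreated bacteria at 45, 90 and 180 min, 11, 17 and 40 for heat-inactivated bacteria, 3 and 4 for untreated against heat-inactivated at 45 and 180 min, 8 and 47 for the interactions, 2222 (alone, 90 against 45), 1918 (coculture, 90 against 45), 1629 (heat-inactivated, 90 against 45) and 2440 (alone, 180 against 90).

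Leaving out 1 compared library at a time gave ranges of 1 to 2, 0 to 0 and 0 to 7 genes for untreated bacteria at 45, 90 and 180 min, 0 to 3, 0 to 8 and 0 to 15 for heat-inactivated bacteria, and 0 to 0, 0 to 1 and 0 to 1 for untreated against heat-inactivated. The interactions gave 0 to 0 with untreated and 0 to 2 with heat-inactivated bacteria. Over time the ranges were 671 to 783 (alone, 90 against 45), 2112 to 2607 (alone, 180 against 45), 891 to 1541 (alone, 180 against 90), 116 to 455 (coculture, 90 against 45), 1966 to 2259 (coculture, 180 against 45), 0 to 217 (heat-inactivated, 90 against 45) and 1318 to 2666 (heat-inactivated, 180 against 45). The 15 and 13 genes for heat-inactivated bacteria at 180 min came without replicates 1 and 3 of mycelium alone, and the 8 at 90 min without heat-inactivated replicate 1. Heat-inactivated 90 against 45 min gave 108 without the library labelled 45 min replicate 2, 217 without that labelled 90 min replicate 3, and 0 otherwise; 1318 came without the library labelled 45 min replicate 3. Depth limits the genes of low level most, since 1 CPM stood for 2.37 to 6.84 counts, depending on the library.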

Other observations

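All tests in this part were chosen after the results were seen, except the counts of other splits for the 13 planned comparisons.

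Genes with nearby identifier numbers changed together over time. In mycelium alone the log2 fold changes from 45 to 180 min of genes 1 number apart had a Pearson correlation of 0.40 across genes, which fell to 0.24 at a distance of 2, 0.18 at 3 and 0.01 at 50. The highest value in 1000 shuffles of the order was 0.036 at a distance of 1, and 0.001 is the smallest p these shuffles can give. Of the 771 genes that rose at least 2-fold, 54 lay in 10 runs of at least 5 consecutive numbers, where the shuffles gave at most 1 such run. Of the 210 that fell at least 2-fold, 7 lay in 1 run, where the shuffles gave 0. In the cocultures, 50 of the 54 rising genes were called as rising too. The run from CADAFUBG00008531 to CADAFUBG00008536, singled out after its values were seen, held 6 genes with a median log2 fold change of 4.43 alone and 5.44 in the cocultures. The 7 falling genes from CADAFUBG00004470 to CADAFUBG00004476 had medians of -3.07 and -3.71. Nearby identifiers also moved together between the cocultures and mycelium alone, with correlations at a distance of 1 of 0.17 at 45 min, 0.13 at 90 min and 0.13 at 180 min, each above the highest of its shuffles (0.032, 0.037 and 0.037). At 180 min the correlation was 0.12 for heat-inactivated bacteria against mycelium alone and 0.13 for untreated against heat-inactivated bacteria. Shuffles of the order cannot tell an effect of bacteria from neighbours that vary together between libraries. None of the genes in the 11 runs was called between the cocultures and mycelium alone at 180 min by edgeR, where 2 of all genes were called.

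Reads shared between overlapping genes would join direct neighbours only, but the correlation at a distance of 3 was still 0.176, above the highest of the shuffles (0.047). A shared level of neighbours, with change depending on level, is argued against by a correlation of 0.375 at a distance of 1 after that trend was removed. A candidate explanation is that the numbers follow the genome and that neighbouring genes, such as those of fungal biosynthetic clusters, were switched together. The files used here give no coordinates, so that this stays untested.

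Heat-inactivated replicate 2 labelled 45 min and replicate 3 labelled 90 min each lay at the other time. On a scale where mycelium alone averaged 0 at 45 min and 1 at 90 min they scored 0.895 and 0.043, where the other libraries ran from -0.018 to 0.309 at 45 min and from 0.883 to 1.03 at 90 min. A near-equal mixture of RNA of both times would place them in between, and the nearer of the 2 lay 0.095 outside a middle range set after the scores were seen. A small share of RNA of the other time could not be told from none. A culture running behind at 90 min would keep its own replicate signature. That library matched its own number worse than another by -0.666, below the lowest of the other 25 libraries (-0.203). But all 3 heat-inactivated libraries labelled 90 min matched number 2 best, with correlations of 0.139, 0.315 and 0.405. Each library was set against the other culture conditions, so a difference of the condition enters the match. A culture running behind therefore stays open. An exchange of the 2 libraries may explain the pattern, since each lay at the other's time and matched the other's number better than its own, by 0.138 or more. The same limit holds for these matches, so cultures running ahead or behind cannot be told apart from an exchange. For replicate 2 labelled 45 min, the own difference of -0.138 lay within the range of the others. Of the 10 splits of the 6 heat-inactivated libraries of 45 and 90 min, the labelled one called 0 genes with edgeR. The split exchanging just these 2 libraries called 2059, which follows from their having been singled out for lying at the other time and adds no support. Under the labels 328 genes had an unadjusted p under 0.05, and DESeq2 called 0.

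More genes differed with untreated bacteria at 45 min once those 2 libraries were left out, 92 in place of 4, and on the scale from 45 to 90 min the 3 cocultures of 45 min scored 0.262, 0.309 and 0.22, against -0.018 to 0.036 in mycelium alone, which sets the 0 of the scale, and 0.071 and 0.095 in the heat-inactivated libraries of 45 min left in. From 45 to 90 min in mycelium alone, 46 of the 73 risers were called as rising and 5 as falling, and all 19 fallers as falling, but that comparison shares the 45 min libraries of mycelium alone. With heat-inactivated bacteria, which share no library with the list, 39 of the 73 were called as rising and 18 as falling (24.7%, 95% Clopper-Pearson interval 15.3% to 36.1%), and 11 of the 19 fallers as falling and 0 as rising. The scores go with a lead of the cocultures in time and the 18 falling genes count against it for the whole list, but a response to bacteria among genes that change with time could give such scores, and a response to heat-inactivated cells at 45 min could make the 18 fall, so that these cannot be told apart. A shift of the 3 libraries of mycelium alone at 45 min stays open, since the design has 1 such group.

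Groups of 3 against 3 make 10 splits, and so no share under 0.05 could be reached in any comparison of 2 groups. For untreated bacteria the real counts at 45, 90 and 180 min were 4, 0 and 2 genes, and the highest of the other splits were 0, 0 and 3. The number of splits as large, the real one included, was 1, 10 and 2. For heat-inactivated bacteria the real counts were 3, 4 and 1 and the highest others 0, 0 and 1 (1, 1 and 2 splits as large). For untreated against heat-inactivated the real counts were 0, 0 and 1 and the highest others 0, 4 and 1 (10, 10 and 2 splits as large). Over time, the real counts of 1280, 2763 and 1491 genes in mycelium alone, 892 and 2596 in the cocultures and 2303 with heat-inactivated bacteria from 45 to 180 min each stood against 0 in every other split. The 92 genes at 45 min with 2 libraries left out also stood against 0, and for 90 against 45 min with heat-inactivated bacteria 10 of 10 splits were as large as the real count of 0. Where the real count is 0 every split is as large by construction, which says nothing about chance. Every other split mixes libraries of both groups, so a large difference between the groups enters the spread within them. Counts of 0 in those splits are therefore partly built in and add little support.

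In replicate 1 of the cocultures at 90 min, 2 features took 31.2% and 18.0% of all counts, 49.2% together, against at most 28.1% in any other library.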
